A study of Mus musculus with 8 samples.

How the data were processed

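Single-cell gene expression and hashtag libraries were made by the authors with a 5' droplet kit from sorted conventional dendritic cells of pooled mice, per the labels' protocols. Cell Ranger 7.1.0, Seurat and the build mm10 are named in the submitters' processing notes. Their settings, and how barcodes were called as cells, are not given in the sources used here. The 3 files examined hold text and no measured values: the barcode list (a sequence of 16 bases and a suffix per cell), the feature list (identifier, name and type of each gene or hashtag) and the hashtag table (name, read pattern and sequence), as deposited. Counts per cell were not analysed here, so no doublet caller was run and droplets with 2 cells were not removed. The labels give the kind of library and its lane, and place no library in a treatment group, since all hashtagged cells were pooled. No sample was therefore compared with another by treatment, and the replicate number of a sample is its lane. The suffixes of the barcodes were not assigned to lanes. No columns of per-sample values were present.

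Barcodes were counted by suffix. Shares of cells loaded are given with exact Clopper-Pearson 95% intervals, and equality of the 4 suffixes was tested by a chi-square statistic against 100000 multinomial draws. Overlaps of sequences between suffixes were turned into a pool size as the sum of products of the barcode numbers divided by the sum of shared sequences, with an exact Poisson interval. Homogeneity of the 6 overlaps was tested against 100000 simulated draws without replacement. Pairs of barcodes at 1 and 2 mismatches were listed exhaustively, and the number within a suffix was compared with 100000 permutations of the suffixes over barcodes (two-sided). These steps were tested on simulated data of 53233 barcodes. With a true pool of 700000, the mean of 20 estimates was 702371, and 19 of the 20 intervals held the true value. Of 300 simulated error copies added to a suffix, an excess of 275 pairs was recovered. The copies were added to random sequences, which hold far fewer pairs at 2 mismatches than the list. For random sequences 337 such pairs were expected, against 25373 in the list. The run therefore does not show how well error copies would be found in the list itself.

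A set of 14 gene lists (159 distinct genes) for dendritic cells, tolerance, nucleic acid sensing, interferon response, retroelement control and cell types outside the sort was fixed before the data were examined, as were the tests above. The text names every list member missing from the gene list and the first 3 members found of each list, and further genes only for shared sequence. One gene list and one value of shared sequence are not reported here. Symbols were matched exactly, then through the synonyms of the RefSeq gene table for GRCm38.p6. Gene identifiers were matched to GENCODE M21 without version numbers. This annotation need not be the one the authors counted with, since 50 identifiers were absent from it and 733 carried another symbol in it. Sharing of transcript sequence was measured as the percentage of a gene's distinct stretches of 50 bases, over all its GENCODE M21 transcripts in the sense direction, that also occur in a transcript of another gene on the list. A threshold of 10% was used to name genes. The read length is not given in the sources used here, so 50 bases is a choice, with 90 bases, the first 500 bases of each transcript, any gene of the annotation, and a restricted transcript set as alternatives. On 3 simulated genes this step returned 37.0% for a true share of 36.9%.

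Alternatives planned before the data were examined were sequences under a single suffix, each suffix left out in turn, Wilson intervals, a pool size from sequences under 3 suffixes, omission of homopolymer runs of 4 or more bases, pairs at 2 mismatches, edit distance for hashtags, and symbol matching without case or with older symbols. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.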

Results

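The study profiled single conventional dendritic cells from the small intestine of C57BL/6J mice that had or had not received an anti-reverse transcriptase treatment for 7 days, with 3 mice in each condition. Conventional dendritic cells are antigen-presenting cells of the intestinal wall that carry dietary and microbial antigens to T cells. They were sorted as CD11c-high, MHC class II-high leukocytes after exclusion of B cells, T cells, NK cells and CD64-positive cells. Each mouse and tissue was marked with an oligonucleotide-labelled antibody (a hashtag), all cells were pooled, and 40000 cells were loaded on each of 4 lanes of a droplet device. The 8 samples were 4 gene expression libraries and 4 hashtag libraries, one of each per lane. Treated and untreated cells were therefore mixed in every library, and a cell's treatment could be read only from its hashtag counts. The values examined were the list of cell barcodes, the list of counted genes and hashtags, and the table of hashtag sequences. Expression and hashtag counts per cell were not analysed here, so no gene is described as higher or lower in treated mice, and the sequencing depth per cell is unknown. What could be compared was the layout of the hashtags, the number of cell barcodes, and which dendritic cell, interferon and retroelement-related genes the experiment was set up to count.

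The hashtags laid out a complete design of tissue by treatment. The feature list named 24 hashtags over 4 tissues (duodenum, jejunum, ileum and mesenteric lymph node), with 3 control and 3 anti-reverse transcriptase hashtags for each tissue. The hashtag table gave sequences for 18 of these, 3 control and 3 treated for each of the 3 segments of the small intestine. The remaining 6 hashtags, all named for mesenteric lymph node, appeared on the feature list only. The sample labels describe small intestine only, so whether lymph node cells were in the pool is not known here. The barcode list did not give the tissue of a cell, and the number of cells from each tissue was not analysed here.

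Each hashtag was a sequence of 15 bases that began after 10 unspecified bases at the start of read 2. The duodenal control hashtags numbered 1, 2 and 3 were ACCCACCAGTAAGAC, GGTCGAGAGCATTCA and CTTGCCGCATGTCAT, and the duodenal treated hashtags were AAAGCATTCTTCACG, CTTTGTCTTTGTGAG and TATGCTGCCACGGTA. In the jejunum, the control hashtags were GAGTCTGCCAGTATC, TATAGAACGCCAGGC and TGCCTATGAAACAAG, and the treated hashtags were CCGATTGTAACAGAC, GCTTACCGAATTAAC and CTGCAAATATAACGG. In the ileum, the control hashtags were CTACATTGCGATTTG, CTTTCGCCAACTCTG and CCCTCTCTGGATTCT, and the treated hashtags were GATGTATCCGTTGTC, CTGCCGTTGTGCTAT and GAATTAAGAGCCGGA. Over the 153 pairs of hashtags, the number of mismatched bases ranged from 7 to 15 with a median of 11. The 2 closest pairs, at 7 mismatches, were the third duodenal control with the second ileal control, and the third duodenal treated with the first jejunal control. Among these 18 hashtags, a read with up to 3 mismatches thus remained nearest to its own sequence; the 6 lymph node hashtags were not compared. Across the 81 pairs of a control with a treated hashtag the lowest distance was also 7.

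The pooled cells gave 53233 cell barcodes, 33.3% of the 160000 cells loaded (exact Clopper-Pearson 95% interval, 33.0% to 33.5%). Each barcode carried a suffix from 1 to 4. Which suffix belonged to which lane is not stated in the sources used here, so the suffixes are reported by number. Whether droplets with 2 cells were removed before the list was made is not given in the sources used here, so a barcode need not be a single cell. Suffix 1 held 13325 barcodes, suffix 2 held 12859, suffix 3 held 12700 and suffix 4 held 14349, with a median of 13092. As shares of the cells loaded on a lane, these were 33.3%, 32.1%, 31.8% and 35.9%. The largest suffix held 1.13 times as many barcodes as the smallest (exact 95% interval, 1.10 to 1.16). The 4 numbers differed by more than counting error (chi-square of 124 against equal numbers, p = 1e-05, the smallest that 100000 multinomial draws can give). These intervals and the test cover counting error only. The lanes were loadings of one pool and not separate mice, so the spread between suffixes is technical.

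**Figure D1:**
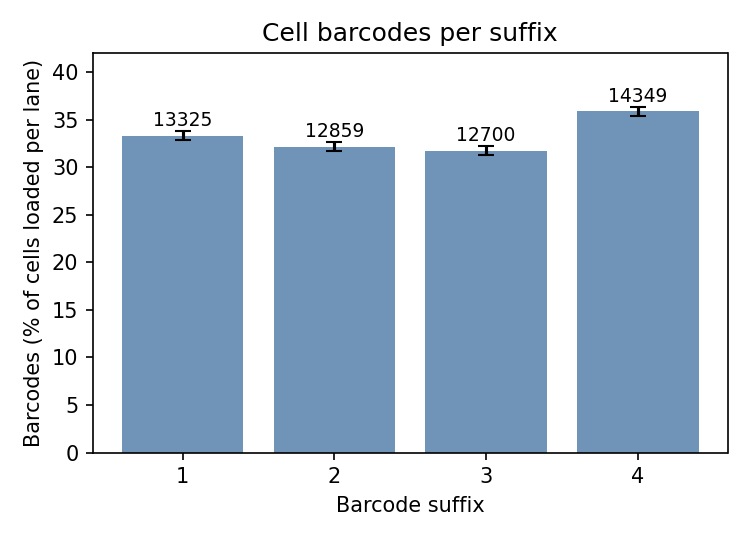
Cell barcodes under each of the 4 suffixes, as a percentage of the 40000 cells loaded per lane (vertical axis, from 0). Error bars are exact 95% binomial intervals and the number above each bar is the count of barcodes, from 12700 under suffix 3 to 14349 under suffix 4.

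Barcode sequences did not identify a cell without the suffix. The 53233 barcodes used 51800 distinct sequences, and 1413 sequences (2.73%, exact 95% interval 2.59% to 2.87%) occurred under more than 1 suffix. Of these, 1393 occurred under 2 suffixes, 20 under 3 and 0 under 4. As a result, 2846 barcodes, or 5.35% of the list, shared their sequence with a cell of another suffix. The 6 pairs of suffixes shared between 214 and 268 sequences. If barcodes were drawn evenly from one pool, these overlaps gave a pool of 730784 sequences (95% Poisson interval, 694152 to 769865). The 6 overlaps did not differ beyond simulated draws from a single pool of that size (chi-square of 2.67 over the 6 pairs, p = 0.74 from 100000 draws), and such draws gave a mean of 17.3 sequences under 3 suffixes (95% of draws, 10 to 26). No pair of sequences differed at a single base, against 15.0 pairs for random sequences. With no such pair, the planned comparison of pairs within and between suffixes had no content. At 2 mismatches there were 25373 pairs of distinct sequences, against 337 for random sequences, so the sequences were not spaced like random ones. Counted with their suffixes these made 26777 pairs of barcodes, of which 6740 shared a suffix. Permuting the suffixes gave a mean of 6710 (95% of permutations, 6571 to 6849; two-sided permutation p = 0.67).

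The gene list held 32285 genes, and 32235 of their identifiers (99.8%) were found in the GENCODE M21 annotation of GRCm38, the assembly also called mm10. Coordinates below are from that annotation. All chosen marker genes of dendritic cells were on the list. These included 9 of 9 markers of conventional type 1 dendritic cells, among them the chemokine receptor gene Xcr1 (chromosome 9, 123852315 to 123862029), the dead-cell receptor gene Clec9a (chromosome 6, 129408862 to 129424763) and the transcription factor gene Irf8 (chromosome 8, 120736358 to 120756694). All 10 markers of conventional type 2 dendritic cells were listed, among them Sirpa (chromosome 2, 129592835 to 129632228), Irf4 (chromosome 13, 30749226 to 30766976) and Itgam, which encodes CD11b (chromosome 7, 128062640 to 128118491). The 7 general dendritic cell and sort genes were listed, beginning with Itgax, which encodes CD11c, the cytokine receptor gene Flt3 and the transcription factor gene Zbtb46. So were the 8 genes of mature or migratory dendritic cells, beginning with Ccr7, the receptor that guides migration to lymph nodes, Fscn1 and Ccl22.

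The title of the study names tolerance to dietary antigens and endogenous retroelements, and genes of both subjects were looked up. All 10 genes for tolerance and induction of regulatory T cells were listed, among them the retinoic acid-producing enzyme gene Aldh1a2 (chromosome 9, 71215789 to 71296243), Itgb8, part of an integrin that activates TGF-beta (chromosome 12, 119158022 to 119238802), and Tgfb1 (chromosome 7, 25687002 to 25705077). The 12 antigen processing and presentation genes were listed, including Cd74, Ciita and H2-DMa. Of 14 nucleic acid sensing genes, 13 were found by symbol, including the DNA sensor gene Cgas (chromosome 9, 78430526 to 78443237) and the RNA sensor gene Ifih1 (chromosome 2, 62595798 to 62646255). The adaptor gene Sting1 was present under its older symbol, Tmem173 (chromosome 18, 35733679 to 35740554). All 19 genes that silence or restrict retroelements were listed, beginning with Trim28, Setdb1 and Samhd1.

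Members were missing from the interferon response list and from the list of genes of retroviral or retrotransposon origin. Of the 19 interferon response genes, 17 were on the list, including Isg15, Ifit1 and Ifit2. The antiviral GTPase genes Mx1 and Mx2 were not. GENCODE M21 places Mx1 at chromosome 16, 97447035 to 97462907, as a protein-coding gene, and Mx2 at chromosome 16, 97535308 to 97560900, as a polymorphic pseudogene, a gene that is intact in some strains and broken in others. Reads from either gene could not have been counted under its name with this gene list. Of 21 symbols chosen for genes of retroviral or retrotransposon origin, 18 were on the list, including the syncytin genes Syna and Synb and the retrovirus restriction gene Fv1. The symbols Ervpb1, Erv31 and Emv2 were not, and they were gene symbols in neither GENCODE M21 nor the RefSeq gene table. Their absence therefore need not mean that the gene list left out a gene. Over the 14 lists, 153 of 159 distinct genes were found by exact symbol and 154 after the older symbol was allowed.

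Genes of cells that the sort should have removed were also countable. All 10 T, B and NK cell genes (beginning with Cd3e, Trbc1 and Trbc2), all 10 macrophage, monocyte and plasmacytoid dendritic cell genes (beginning with Fcgr1, which encodes CD64, Adgre1 and C1qa) and all 6 epithelial and stromal genes (beginning with Epcam, Krt8 and Fabp1) were listed. Their levels, and so the purity of the sort, were not analysed here.

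By gene class, the list held 21702 of 22028 protein-coding genes of GENCODE M21 (98.5%), 9830 of 10155 long non-coding genes (96.8%) and 697 of 702 immunoglobulin and T cell receptor genes or segments (99.3%). Pseudogenes of immunoglobulin or T cell receptor types were counted in that last class. Outside it, the list held 1 of 9941 processed pseudogenes and 5 of 3376 other pseudogenes. Processed pseudogenes are gene copies made by reverse transcription of a messenger RNA. None of 6115 small or ribosomal RNA genes and none of 3219 loci awaiting experimental evidence were listed. The feature list had genes and hashtags as its only feature types, and no feature type for retroelement families.

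**Figure D2:**
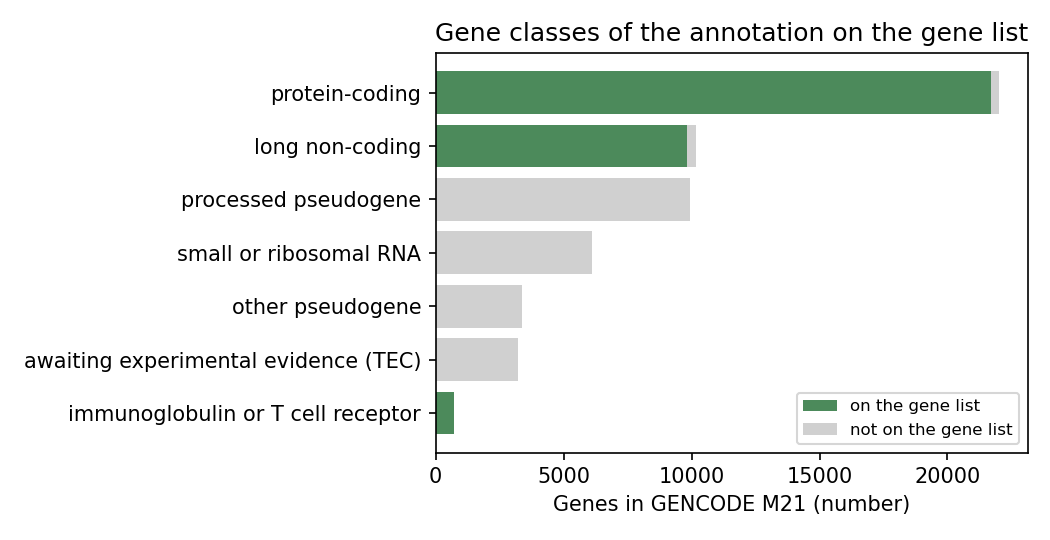
Number of genes in each class of the GENCODE M21 annotation (horizontal axis), divided into those on and not on the gene list of the study. Protein-coding and long non-coding genes are almost fully on the list (98.5% and 96.8%), and 1 of 9941 processed pseudogenes is.

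Some of the chosen genes shared transcript sequence with another gene on the list. The sequence of a read from a shared stretch does not tell such genes apart. How reads of this kind were counted was not examined. The comparison of shared sequence was chosen after the gene list had been seen. Of 154 listed genes, 94 shared no stretch of 50 bases with any other gene on the list, and 14 shared at least 10% of their stretches. In the first 500 bases of the transcripts, nearer to the end a 5' kit reads, 22 genes shared at least 10%. The highest share was that of Trex1, the exonuclease that degrades cytosolic DNA, at 95.8%. These shares are with all other genes on the list together. The gene sharing most with Trex1 was Atrip, which overlaps it on the same strand. With the restricted transcript set, the share of Trex1 was 37.5%. That set left out readthrough transcripts and types other than coding, long non-coding and immune receptor. From protein-coding genes it kept no long non-coding types. The retrotransposon-derived genes Rtl8a and Rtl8b shared 82.5% and 80.0% of their stretches, and each was the gene sharing most with the other. Synb shared 75.9%, most with Gm27179. Among interferon response genes, Oas1a shared 57.6%, most with Oas1g, and Ifit3 shared 51.2%, most with Ifit3b. Restriction factor gene Trim5 shared 29.7%, most with Trim12c. Among antigen processing and presentation genes, H2-DMb1 shared 22.7% with other genes and H2-D1 12.8%. Among markers of conventional type 2 dendritic cells, Clec4a4 shared 15.7% and Mgl2 13.1%. The T cell receptor constant genes Trbc2 and Trbc1 shared 44.0% and 40.5%, and Ly6c2 shared 14.4%. Shares that moved by over 1.5 times were those of Trim5, H2-DMb1, Ly6c2, Mgl2 and H2-D1 with stretches of 90 bases (12.0%, 13.2%, 7.27%, 4.86% and 3.98%) and those of Trim5, Trbc1, Clec4a4 and Ly6c2 in the first 500 bases (61.2%, 62.7%, 25.3% and 22.0%). With the restricted transcripts, the share of Ly6c2 was 31.2%, and that of Trex1 was the only other to move by as much. In all but Trex1, the gene with which the most stretches were shared lay at a separate locus.

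**Figure D3:**
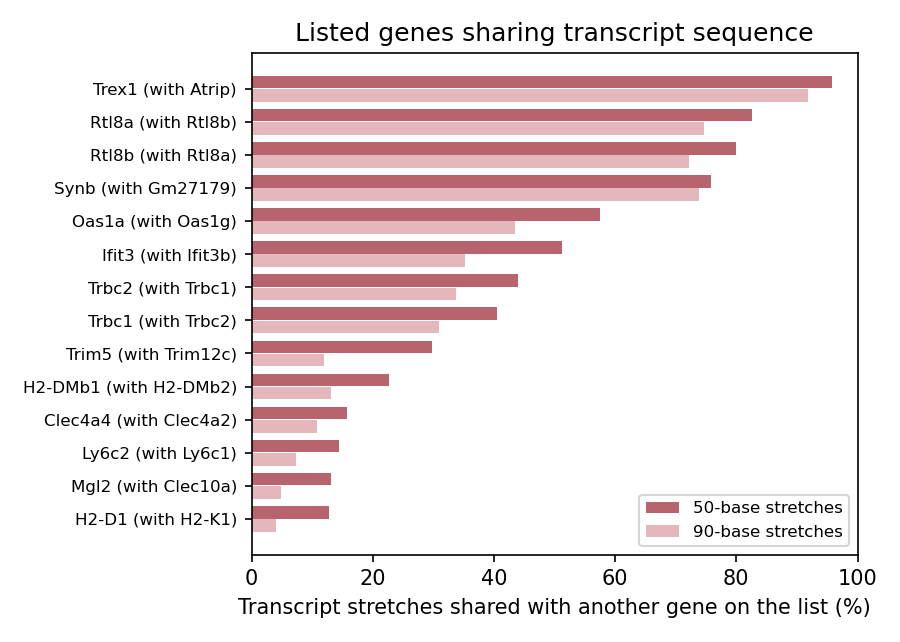
Percentage of each gene's transcript stretches of 50 bases (dark) or 90 bases (light) that also occur in another gene on the list, for the 14 listed genes at 10% or more; the gene sharing most is in brackets. Trex1, Rtl8a, Rtl8b and Synb head the plot, with 95.8%, 82.5%, 80.0% and 75.9% at 50 bases. With the restricted transcript set, which is not plotted, these shares were 37.5%, 82.5%, 80.0% and 75.8%.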

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

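The difference between suffixes kept its side of the threshold under each alternative run, with a ratio of largest to smallest between 1.05 and 1.13 over the 4 omissions of a suffix. The lowest was without suffix 4 (chi-square statistic against multinomial draws, p = 2.10e-04). Leaving out suffix 1 or suffix 2 keeps the largest and the smallest suffix, so the ratio of 1.13 could not change there. Leaving out barcodes with a neighbour at 1 mismatch removed none, so that alternative could not change it either. Counting only sequences found under a single suffix lowered the share of loaded cells from 33.3% to 31.5%, because it removes barcodes by construction. The pool size was 685796 from sequences under 3 suffixes, against 730784 from pairs; its interval, 551839 to 877477, rests on 20 sequences and holds the main value. It ranged from 720184 to 760004 when each suffix was left out. At 2 mismatches 6740 pairs fell within a suffix, against 0 at a single mismatch, since the list holds no closer pairs. The lowest distance between hashtags was 5 by edit distance, against 7 by mismatches, as insertions and deletions are then allowed. The number of listed genes at 10% or more shared sequence was 14, and 22 in the first 500 bases, which lie nearer to the end a 5' kit reads. It was 11 with 90 bases, 19 against any gene of the annotation and 14 with the restricted transcripts, an alternative set chosen, like the others for shared sequence, after seeing the data. No paired analysis was possible because the lists examined here hold no value per library and assign no barcode to a treatment. The treatment of a barcode could be read only from its hashtag counts, which were not analysed here. Depth per cell is unknown, which leaves open how many of the barcodes are cells of use.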

Other observations

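The tests of suffix 4, of missing coding genes and of shared sequence were chosen after the results were seen. Sequence sharing also marked genes below the 10% level over whole transcripts. In the first 500 bases, Ifit1 shared 29.5% of its 50-base stretches with other listed genes, Apobec3 16.9%, Clec9a 16.0%, Ccr9 15.9%, Rnaseh2a 13.4%, Klrb1c 11.9%, H2-K1 10.9% and Clec10a 10.9%. For Apobec3, Clec9a, Ccr9 and Rnaseh2a the gene sharing most over whole transcripts overlapped on the same strand. With the restricted transcript set, the share over whole transcripts was 6.05% for Apobec3, 0% for Clec9a, 3.90% for Ccr9 and 8.77% for Rnaseh2a. With all transcripts these shares were 6.53%, 4.02%, 2.13% and 7.86%. Apobec3 is a retroelement restriction factor gene and Rnaseh2a encodes part of an enzyme that cuts RNA in RNA-DNA hybrids. Itgam, a marker of type 2 dendritic cells, shared 0% of its stretches with listed genes and 66.3% with genes of the whole annotation. Whether its partner was a separate copy or an overlapping gene model was not tested. The genes named here were chosen after their values were seen.

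Suffix 4 held 1388 more barcodes than the mean of the other suffixes (12961), a surplus of 10.7%. It was singled out because it was the largest, and its gap to the next suffix was 0.621 of the whole range, below the 95% critical value of Dixon's test for 4 values, so it did not stand apart from the spread of the suffixes by that test. If extra barcodes were error copies of real ones, they should lie close to them within the suffix. Within suffix 4 there were 1916 pairs at 2 mismatches, against a permuted mean of 1946 (95% of permutations, 1862 to 2030). The upper limit of the excess was 54 pairs, below the surplus of 1388. The simulated run did not show how well error copies would be found in this list. Copies at more mismatches were not tested. If barcodes had been carried over from other lanes, suffix 4 should share more sequences with them: it shared 790, which is 1.08 times the rate of the other pairs (exact 95% interval, 0.97 to 1.19, binomial p = 0.16), or at most 129 in excess. The excess of pairs at 2 mismatches and the excess of shared sequences each fell short of the surplus by these limits. How many error copies could go unseen in this list was not established. Unequal loading, capture or cell calling between lanes stays open and was not tested, and no biological explanation was tested, since the lanes came from one pool.

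Of the protein-coding genes of GENCODE M21, 326 were not on the gene list. Among them 221 (67.8%) had a transcript tagged as readthrough into a neighbouring gene, against 47 of 21702 genes on the list (0.217%; Fisher's exact test, two-sided p at most 1e-300). This is consistent with a rule that removed readthrough genes before counting. The rule cannot account for Mx1, which has 0 readthrough transcripts. A candidate explanation for Mx1 is that annotations disagree on whether it is coding: the RefSeq table lists it as a transcribed pseudogene. Of the 41 missing coding genes without readthrough that the RefSeq table names, 23 (56.1%) were not protein-coding there, against 338 of 20773 genes on the list (1.63%). Only 41 of 105 such genes (39.0%) had a RefSeq entry under their symbol, so this check is void and the explanation stays open. An interferon score computed from this gene list would lack Mx1 and Mx2.

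If the hashtags were evenly represented, 5.56% of droplets with 2 cells would carry a single hashtag with 18 hashtags and 4.17% with 24. This is arithmetic on the hashtag list and not a measured doublet rate.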
